A study of Mus musculus with 12 samples.

How the data were processed

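The libraries were QuantSeq 3′ mRNA-Seq FWD libraries (Lexogen) from RNA purified with RNeasy Plus Micro columns, per the labels' protocols. The deposited values were raw read counts per gene symbol, made by the authors with HISAT2 2.2.1 against mm10 and HTSeq 0.9.1, per the submitters' processing notes. Those notes also name DESeq2 1.34.0 for the authors' own comparison, which was not used here. The gene annotation, the strand setting, trimming and read filters were not given in the sources used here. Each of the 12 files held 35976 gene symbols, and 32501 of them (90.3%) were matched by symbol to a RefSeq table of the same assembly for positions.

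Counts were compared in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Library sizes were scaled with TMM, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. That left 11548 genes in a fit of 6 groups over 12 libraries with 6 residual degrees of freedom and 8.68 prior ones, and at most 0.27% of a library's counts lay outside them. A gene changed when edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The 9 contrasts were 7 between groups and 2 interactions. CPM used TMM sizes. A prior count of 2 entered the log2 levels behind camera, fry, the replicate comparisons and the correlation of age and KO changes. EdgeR's log2 fold changes of genes, and the list medians made from them, used its smaller default. Where all libraries of a group had 0 counts, the fold was bounded with 3 counts over the group. For 1 to 3 counts the ratio was given with an exact conditional 95% interval. These bounds and intervals cover counting error only, and not a transcript lost from a library.

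The contrasts, the tests, the 34 gene lists and the naming rule were fixed before the data were examined. The lists covered NAD metabolism, calcium signalling downstream of cyclic ADP-ribose, long-term HSC identity, quiescence and CDK inhibitors, the HSC ageing signature, the cell cycle, energy metabolism, stress and inflammatory responses, growth, ribosomal proteins, blood lineages, stroma and sex-linked genes. They held 886 members, of which 9 were not in the files, and a gene can belong to several lists. Each was tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the 34 lists of a contrast. Members were also counted by their gene tests, over all genes and adjusted over the list alone.

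Genes were named by rule. Cd38 came first. In each contrast between groups, the 10 largest rises and the 10 largest falls were named among changed genes with a mean of at least 5 CPM over the 4 libraries and both libraries of a group above both of the other. Predicted gene models were counted and not named. With fewer than 5 such genes, the 5 with the smallest p-values at that level were given as values. For interactions the 5 smallest p-values that passed were named, or the 3 smallest when none did, and for each list 2 to 4 members with the smallest adjusted p. A few genes that met the rule are not reported here.

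Alternatives were RLE scaling, no filter, DESeq2, the libraries of a contrast alone, a replicate block, each library left out in turn, and an estimated correlation for lists. Added after the data had been seen were limma voom with a weight per group, the 8 fresh libraries alone, list tests with a replicate block or on the libraries of a contrast alone, and further uses of the fit of the 4 stimulated libraries, namely the naming rule, the linked genes and its own libraries left out in turn.

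The gene tests and camera at the preset correlation were tested on simulated data for the 7 contrasts between groups. In these data 200 of 11548 genes were changed by log2 1 to 3. Counts were drawn with each gene's mean over all 12 libraries, the real library sizes and each group's spread for genes of that level. A gene that varies more between replicates than others of its level was thus not simulated. In stimulated cells edgeR on 4 libraries recovered 38.8%, 83.6% and 95.5% of the changes of log2 1, 2 and 3. In the fresh KO comparisons DESeq2 made 572 false calls in young and 700 in old cells, and edgeR on 12 libraries made 19 and 20. Of 100 unchanged lists, camera gave 1 to 4 an unadjusted p under 0.05 per contrast, and a raised list was found higher in all 7 contrasts. Simulated genes were drawn independently, so this does not show how camera fares where the genes of a list vary together. The interactions, fry and camera with an estimated correlation were not run on simulated data.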

Results

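Transcripts were counted in mouse haematopoietic stem cells (HSCs), sorted as cells without lineage markers that carried c-Kit and Sca-1, from wild-type (WT) animals and from animals labelled as knockout (KO) for Cd38. Cd38 encodes a membrane enzyme that consumes NAD and makes cyclic ADP-ribose. The 12 libraries formed 6 groups of 2: freshly isolated cells from animals aged 2 months (young) or 24 months (old), and cells of young animals after 24 hours with cytokines outside the body, each WT and KO. The stated aim was to learn how CD38 acts on stem cells at rest, during activation by cytokines and in age. Total counts per library were 1600155 and 1753184 in young fresh WT, 1963635 and 1921304 in young fresh KO, 2792521 and 2801629 in stimulated WT, and 3249721 and 2692245 in stimulated KO. The old fresh libraries had 4167857 and 3796591 counts in WT and 4709097 and 5164720 in KO. The old libraries were all deeper than the young fresh ones, so age went with depth and with whatever else set the library sets apart. Levels are given in CPM, the count scaled to the library's total, as the mean ± SD of the 2 libraries of a group (n = 2), and fold changes are log2 ± SE. Adjusted p-values for genes come from edgeR's quasi-likelihood test and those for gene lists from limma's camera, both with the Benjamini-Hochberg method. The labels do not say whether libraries came from separate animals, so every p-value measures only the spread between these samples.

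Stimulated libraries resembled each other far more closely than fresh ones did. At equal depth, 12463 to 12706 genes were detected in a stimulated library and 8907 to 9898 in a fresh one. The correlation of log2 levels across genes, which are not independent replicates, was 0.959 and 0.954 between the replicates of stimulated WT and KO, and 0.704 to 0.746 between the replicates of the fresh groups. The dispersion between replicates was 0.0327 and 0.0391 in the stimulated groups and 0.963 or more in the fresh ones. Genes absent from 1 replicate and above 50 CPM in the other numbered 51 and 126 in young fresh WT and KO, 42 and 30 in old fresh WT and KO, and 0 in either stimulated group. Xist, the transcript of the inactive X chromosome, had 0 counts in young fresh WT replicate 1, where Y-linked genes summed to 200 CPM. The other 11 libraries had Xist at 198 to 745 CPM and Y-linked genes at 6.62 CPM or less, so sex differed within the young fresh WT group.

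**Figure D1:**
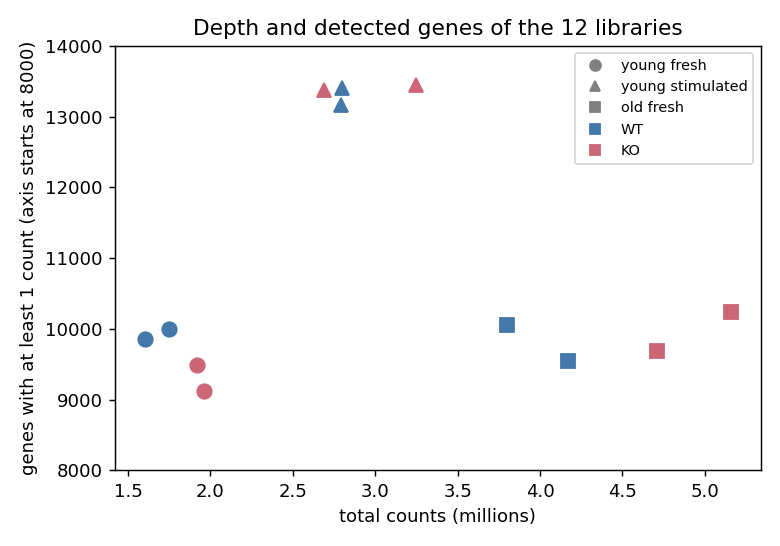
Genes with at least 1 count (vertical axis, not starting at 0) against total counts (horizontal axis) for the 12 libraries, 1 mark per library, with shape for age and treatment and colour for genotype (n = 2 per group). The 4 stimulated libraries lie between 13163 and 13450 genes, above all 8 fresh libraries, which lie between 9116 and 10231.

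Cd38 itself (mouse build mm10, chromosome 5, 43868809 to 43912374) was counted in every library, KO libraries included. Young fresh WT libraries had 17.6 and 24.6 CPM and young fresh KO libraries 62.8 and 31.9 CPM. Young stimulated WT libraries had 0.998 and 8.58 CPM and young stimulated KO libraries 3.59 and 2.32 CPM. Old fresh WT libraries had 74.4 and 41.4 CPM and old fresh KO libraries 13.2 and 19.9 CPM. None of the 3 differences between genotypes passed edgeR's quasi-likelihood test, with log2 changes of 1.17 ± 1.14 (adjusted p = 0.759), -0.69 (adjusted p = 1) and -1.81 ± 1.15 (adjusted p = 0.592) in these 3 settings. The labels do not give the deleted part of the gene, and a tag at the 3′ end can lie outside it, so these counts check the genotype in neither direction. The genotypes are therefore named as labelled. Kit, which encodes c-Kit, had 191 to 423 CPM over the 12 libraries and did not pass between genotypes, with adjusted p = 0.727 in young fresh, 1 in young stimulated and 0.475 in old fresh cells. The same held for Ly6a, which encodes Sca-1, at adjusted p = 0.914, 1 and 1, and for Nampt, a rate-limiting enzyme of NAD salvage, at 0.957, 1 and 0.998. Nor did the NAD-dependent deacetylase gene Sirt1 pass, at 1, 1 and 0.835, or the NAD-consuming DNA repair gene Parp1, at 0.984, 1 and 0.49. Bst1, a neighbour of Cd38 with related activity, had 0 counts in every fresh group and in stimulated KO, and 4.3 ± 1.9 CPM in stimulated WT, too few for the test. Fos, an immediate early transcription factor, had 0 counts in young fresh cells of both genotypes and 45.9 ± 18 CPM in stimulated KO against 21.2 ± 12 CPM in stimulated WT (adjusted p = 1). In old fresh cells it had 0 counts in KO and 6.64 ± 9.4 CPM in WT (adjusted p = 0.4).

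Whether CD38 bears on activation by cytokines was addressed by comparing the stimulated KO and WT libraries. Genes of long-term stem cells were higher in the libraries labelled KO, and genes of lymphoid-primed and B-lineage cells were lower. Aldh1a1, a retinaldehyde dehydrogenase, stood at 138 ± 29 CPM in KO and 33.1 ± 1.6 CPM in WT, and Timp3, an inhibitor of matrix metalloproteinases (chromosome 10, 86300412 to 86349505), at 90.2 ± 32 and 16.2 ± 2.3 CPM. Dntt, the polymerase that adds bases where antigen receptor segments join (chromosome 19, 41029275 to 41059525), stood at 47.6 ± 28 CPM in KO and 571 ± 280 CPM in WT. In the fit of these 4 libraries alone, 129 of 10494 genes changed by edgeR's quasi-likelihood test, 80 higher and 49 lower in KO. In the fit of all 12 libraries, where these genes take the spread of the fresh libraries, edgeR called 0 of 11548 genes, and 57 had an unadjusted p under 0.05 where chance gives 577. On the same 12 libraries DESeq2 called 4 genes and limma voom with a weight per group 227. In simulated counts with the spread of these groups, the 4-library fit recovered 145 of 200 changed genes with 5 false calls and the 12-library fit 21 with 0 false calls. The simulated spread followed a gene's level alone, so genes that varied more between replicates than others of their level were not covered. Among the genes with the smallest p in the 12-library fit, Sult1a1 and Tgm2 had adjusted p = 0.462, Clca3a1 0.89, Gng11 0.902 and Aldh1a1 0.996.

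The naming rule was applied to the 4-library fit after its calls were seen, and 123 of the 129 genes met it, 3 of them without a gene name. Evc2, with 0 counts in WT and 14 and 32 in the KO libraries, passed the test but not the rule, whose 5 CPM apply to the mean over all 4 libraries. The 10 with the largest rise included Clca3a1, a regulator of chloride channels (4.34 ± 0.57, adjusted p = 0.00215 by edgeR), Eya4, a transcriptional coactivator (4.19), Vwf, the platelet adhesion protein von Willebrand factor (3.38 ± 0.65), and Rhof (2.68). The others were the sulfotransferase gene Sult1a1 (2.60 ± 0.40), the actin regulator gene Phactr1 (2.58), the sialomucin gene Podxl (2.54), Timp3 (2.49 ± 0.28, adjusted p = 0.000869), the stress-induced gene Nupr1 (2.48 ± 0.40) and Sdpr, which encodes a coat protein of caveolae (2.39 ± 0.30, adjusted p = 0.0018). Sema3d, a secreted guidance protein, had 0 counts in KO and was at least 25.3-fold lower than its 11.4 ± 8.1 CPM in WT. Il7r, the receptor for the lymphoid growth factor IL-7, had 2 counts in KO and 137 in WT, a ratio of 75.4 (95% counting interval 20.5 to 629). Ptger2, a prostaglandin E2 receptor, had 2 counts against 70, a ratio of 38.5 (10.3 to 324). Then came Arpp21 (-4.47), Cmah (-4.23), Bfsp2 (-4.01), the B-lineage transcription factor gene Ebf1 (-3.82, adjusted p = 0.0299), AA467197 (-3.82), Dntt (-3.55 ± 0.34, adjusted p = 0.000285) and Vpreb1, part of the surrogate light chain of early B cells (-3.08, adjusted p = 0.0142). Intervals and floors here cover counting error only, and a floor is 3 counts over the libraries of a group. The 2 WT libraries differed in the lymphoid genes: Dntt stood at 372 and 769 CPM, Il7r at 5.99 and 39.3 CPM and Ebf1 at 5.66 and 34.7 CPM in WT replicates 1 and 2.

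Left out in turn, the stimulated libraries moved the 4-library count from 129 to 296 without WT replicate 1, 129 without WT replicate 2, 48 without KO replicate 3 and 24 without KO replicate 4. Of the 129 genes, 121, 81, 38 and 23 were called again in these fits, and the sign was kept by all 129 in the first 3 and by all 128 still tested in the last. Of the 20 genes named by rule, 20, 10, 9 and 6 passed again. Clca3a1, Timp3, Sdpr and Dntt passed in each of the 4, with log2 changes of 3.84 to 5.12, 2.08 to 2.82, 1.90 to 3.13 and -4.33 to -2.93. Without WT replicate 2, Ebf1 stood at -1.97 (adjusted p = 0.727 by edgeR), Vpreb1 at -1.69 (0.0675), Il7r at -4.15 (0.345) and Rhof at 2.22 (0.137). Also lost there were Sema3d (0.155), Ptger2 (0.128), Arpp21 (0.354), Cmah (0.504), Bfsp2 (0.547) and AA467197 (0.116). Without KO replicate 3 the genes lost were Nupr1 (2.74, adjusted p = 0.0537 by edgeR), Podxl (2.46, 0.0693), Rhof (0.22), Sema3d (0.138), Il7r (0.169), Ptger2 (0.128), Arpp21 (0.193), Cmah (0.185), Bfsp2 (0.27), Ebf1 (0.317) and Vpreb1 (0.259), and AA467197 stood at -8.52. Without KO replicate 4 Eya4 stood at 2.00 (adjusted p = 0.846 by edgeR), Vwf at 2.53 (0.49), Sult1a1 at 2.07 (0.0943), Nupr1 at 2.16 (0.073) and Rhof at 2.70 (0.232). Also lost there were Sema3d (0.0572), Il7r (0.064), Ptger2 (0.064), Arpp21 (0.0523), Cmah (0.19), Bfsp2 (0.13), Ebf1 (0.0943), AA467197 (0.128) and Phactr1 (0.164). These fits leave a group with 1 library, which is assumed to vary like the other.

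**Figure D2:**
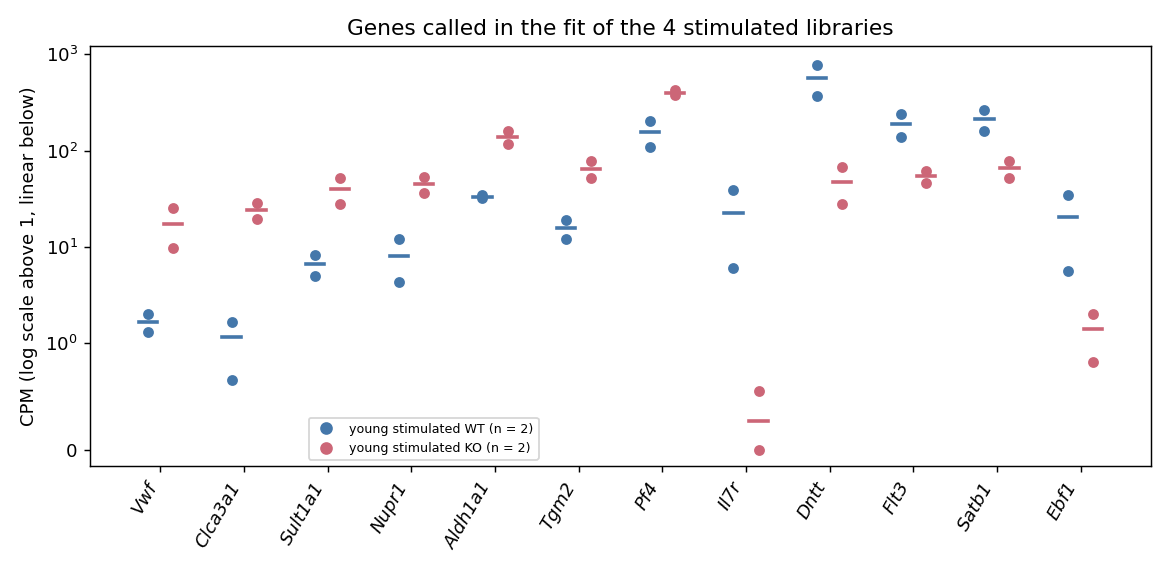
Levels in CPM (vertical axis, log above 1 and linear below) of genes that changed in the 4-library fit (horizontal axis) in stimulated cells, with points for libraries, bars for means and colour for genotype. Aldh1a1 lies at 138 ± 29 CPM in KO and 33.1 ± 1.6 CPM in WT (SD, n = 2), and Dntt at 47.6 ± 28 CPM in KO and 571 ± 280 CPM in WT.

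Of lists, 14 of the 34 fixed gene lists passed camera over the 12 libraries, 6 higher and 8 lower in KO, although no member passed the 12-library test over all genes. The 28 genes of long-term HSC identity were higher (27 of 28 positive, median 1.14, adjusted p = 6.9e-28), and adjusted over the list alone 7 rose and 0 fell. In the 4-library fit 10 of these 28 rose over all genes, among them Tgm2, a transglutaminase, at 64.4 ± 18 CPM in KO against 15.6 ± 4.8 CPM in WT (2.07 ± 0.30, adjusted p = 0.00386 by edgeR). Another was the junction protein gene Esam at 82.4 ± 7.2 against 27.9 ± 4.8 CPM (1.59 ± 0.23). The 41 genes of the HSC ageing signature were higher (median 1.75, and 1.73 with genes at 0 in 1 group placed at their bound, adjusted p = 2.64e-27). Adjusted over the list alone 3 rose, and in the 4-library fit 11 of 33 rose, Aldh1a1 (2.08 ± 0.21), Vwf and Clca3a1 among them. The ageing list shares Slamf1 and Sult1a1 with the identity list. The megakaryocyte and platelet list was higher (16 genes, 15 positive, median 0.85, adjusted p = 9.37e-08), with 3 of 13 higher in the 4-library fit: the platelet chemokine gene Pf4 at 399 ± 34 against 155 ± 66 CPM (1.39 ± 0.21), Rab27b (1.53) and the thrombin receptor gene F2r (0.85). All 17 genes of the lymphoid-primed progenitor list were negative (median -1.69, adjusted p = 4.88e-16), and in the 4-library fit 8 of 16 fell, or 12 when adjusted over the list alone. Flt3, the receptor for a growth factor of lymphoid progenitors, stood at 54.1 ± 11 against 189 ± 73 CPM (-1.77 ± 0.24, adjusted p = 0.0024 by edgeR) and the chromatin organiser gene Satb1 at 65.1 ± 18 against 211 ± 73 CPM (-1.67 ± 0.23). The B cell list was lower (10 genes, 7 negative, median -1.99, adjusted p = 1.42e-09), with Ebf1 and Vpreb1 lower among 8 tested in the 4-library fit. The mast cell and basophil list was lower (9 genes, 8 negative, median -0.62, adjusted p = 0.000151). These 6 lists also passed with an estimated correlation, at adjusted p = 0.00106 for identity, 0.0189 for ageing, 0.0189 for megakaryocyte, 0.0105 for lymphoid-primed, 0.0453 for B cell and 0.0322 for mast cell genes. By fry, which tests whether the genes of a list move on balance 1 way and compares them with no other genes, the identity list alone passed (adjusted p = 0.00371). On the 4 stimulated libraries alone, a test added after these results, 11 of the 14 lists passed with the preset correlation, the B cell list did not (adjusted p = 0.0598), and no list passed with an estimated correlation (smallest adjusted p = 0.602). Single libraries moved these medians: the ageing list stood at 0.94 without KO replicate 4, the lymphoid-primed list at -0.68 without WT replicate 2. The B cell list stood at -3.47 without WT replicate 1, -0.88 without WT replicate 2 and -3.05 without KO replicate 4. The mast cell list stood at -1.01 without KO replicate 3 and at -0.48 without KO replicate 4, where it no longer passed (adjusted p = 0.2). Of the members named here from the 4-library fit, Tgm2, Esam, Aldh1a1, Clca3a1 and Satb1 passed with each library left out. Without KO replicate 3, Flt3 (adjusted p = 0.0537 by edgeR), Pf4 (0.0886), Rab27b (0.149) and F2r (0.093) did not pass, without KO replicate 4 Vwf (0.49), Rab27b (0.0822) and F2r (0.423) did not, and without WT replicate 2 F2r (0.0871) did not.

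The other 8 lists passed with the preset correlation of 0.01 only. G1/S and DNA replication genes were lower (median -0.23, adjusted p = 0.00849, and adjusted p = 0.314 with an estimated correlation). So were G2/M and mitosis genes (-0.35, 0.00201, and adjusted p = 0.0926 with an estimated correlation). Among them Top2a, a topoisomerase of dividing cells, fell in the 4-library fit from 1080 ± 97 CPM in WT to 746 ± 56 CPM in KO (-0.51 ± 0.12, adjusted p = 0.0443 by edgeR). Mitochondrially encoded oxidative phosphorylation genes were lower (-0.15, 0.0214, and adjusted p = 0.117 with an estimated correlation). Lower too were neutrophil and granule genes (-0.41, 0.0315, and adjusted p = 0.379 with an estimated correlation) and monocyte, macrophage and dendritic genes (-0.40, 0.0214, and adjusted p = 0.283 with an estimated correlation). Immediate early genes were higher (0.65, 0.0013, and adjusted p = 0.142 with an estimated correlation), as were cytokine response genes (0.38, 0.00484, and adjusted p = 0.0926 with an estimated correlation). Of the latter, Socs2, a brake on cytokine signalling, rose in the 4-library fit from 21.7 ± 9.5 to 64.5 ± 19 CPM (1.59, adjusted p = 0.0207 by edgeR). Type I interferon genes were higher (0.23, 0.0496, and adjusted p = 0.379 with an estimated correlation), and the antiviral gene Ifitm3 rose in the 4-library fit from 111 ± 20 to 212 ± 0.23 CPM (0.96, adjusted p = 0.00938 by edgeR). Each of these 8 calls ended when a single library was left out. Without WT replicate 1 the calls for immediate early (0.52, adjusted p = 0.0698), cytokine response (0.33, 0.0871), monocyte (-0.32, 0.0871) and interferon genes (0.20, 0.184) ended, and the mitochondrially encoded list stood at -0.39. Without WT replicate 2 those for G1/S (-0.22, 0.125), mitochondrially encoded (-0.09, 0.185), interferon (0.19, 0.179), neutrophil (-0.29, 0.182) and monocyte genes (-0.25, 0.179) ended. Without KO replicate 3 those for G2/M (-0.22, 0.102) and interferon genes (0.14, 0.566) ended, and the neutrophil and monocyte lists each stood at -0.84. Without KO replicate 4 those for G1/S (-0.14, 0.24), mitochondrially encoded (-0.21, 0.2), immediate early (0.08, 0.336), cytokine response (0.18, 0.22), neutrophil (-0.28, 0.533) and monocyte genes (-0.09, 0.438) ended. Top2a did not pass edgeR's test without WT replicate 2 (adjusted p = 0.121), KO replicate 3 (0.204) or KO replicate 4 (0.535), and neither Socs2 (0.0749 and 0.232) nor Ifitm3 (0.122 and 0.064) passed without KO replicate 3 or 4.

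The remaining 20 lists did not pass in stimulated cells. NAD metabolism genes had a median of -0.06 (25 genes, adjusted p = 0.329) and genes of calcium signalling downstream of cyclic ADP-ribose one of -0.03 (26 genes, 0.453). Medians were 0.11 for quiescence and CDK inhibitor genes (0.146), 0.16 for glycolysis (0.453), -0.07 for nuclear-encoded oxidative phosphorylation (0.231), 0.08 for the integrated stress response (0.202) and -0.01 for the unfolded protein response (0.755). They were 0.17 for NF-kB and inflammasome genes (0.273), 0.10 for p53 targets (0.716), -0.08 for MYC and ribosome biogenesis (0.329) and -0.05 for cytosolic ribosomal proteins (0.781). The rest had medians of 0.05 for autophagy and lysosome genes (0.755), -0.66 for T and NK cell genes (0.231), 0.17 for stroma and endothelium (0.755) and 1.35 for the 2 sex-linked genes tested (0.416). For 5 lists the median, the mean and the direction of the test did not share a sign: mitochondrial protein folding stress (median -0.04, mean 0.01, test down, adjusted p = 0.913), cholesterol synthesis (0.08, 0.02, down, 0.905), the antioxidant response (-0.02, 0.12, up, 0.755), the hypoxia response (0.02, -0.03, up, 0.913) and erythroid genes (0, 0.06, up, 0.755). The erythroid carbonic anhydrase gene Car2 rose in the 4-library fit (0.73, adjusted p = 0.0168 by edgeR), and without KO replicate 4 it did not (0.44, adjusted p = 0.424).

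**Figure D3:**
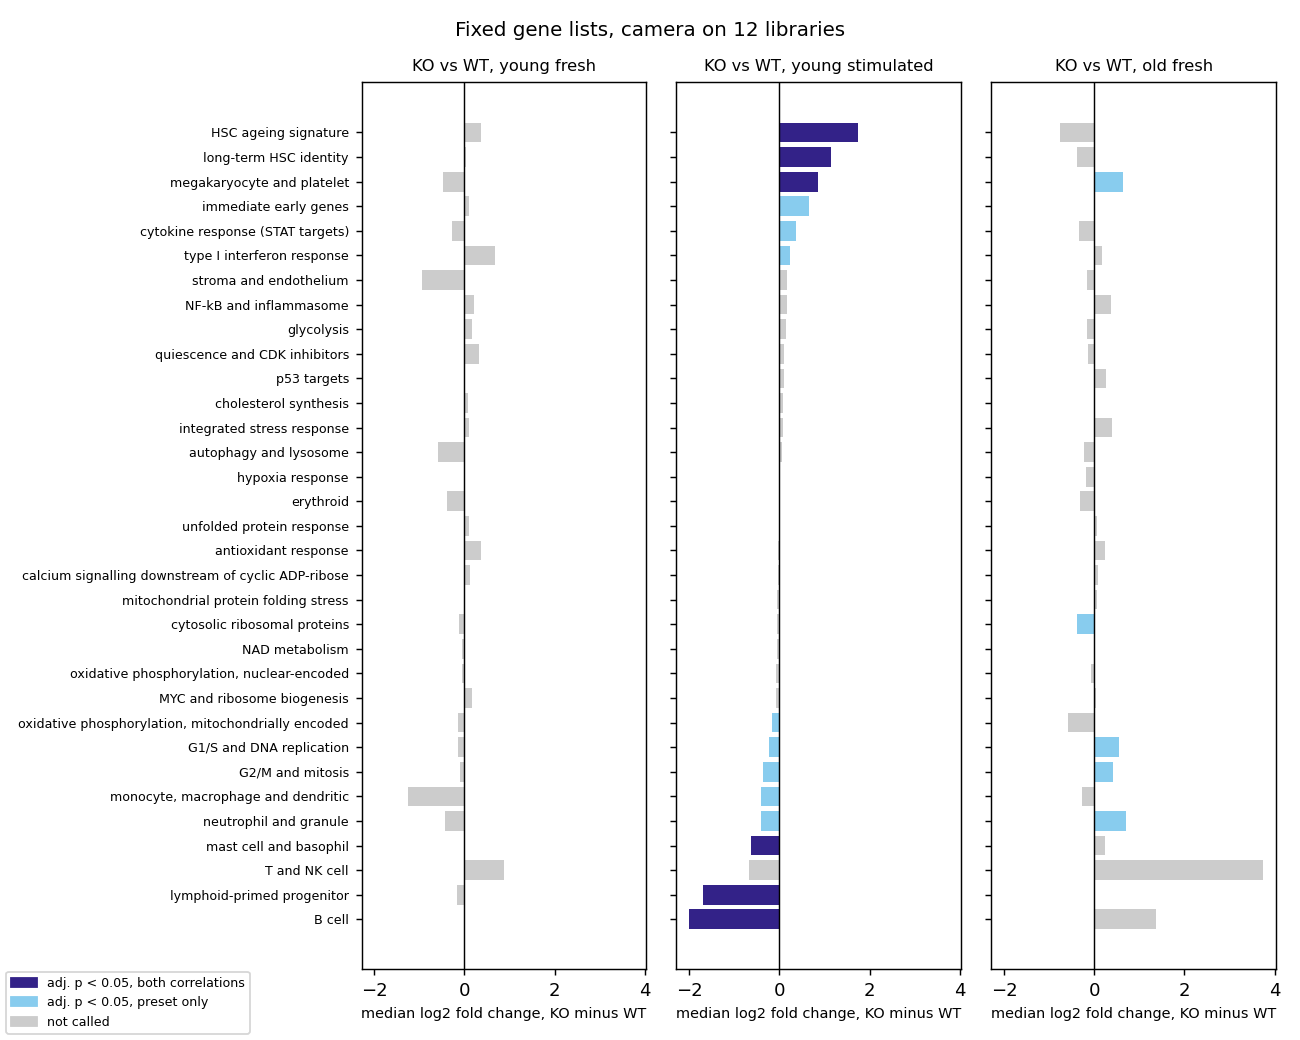
Median log2 fold change of KO minus WT (horizontal axis) for 33 gene lists (vertical axis, sex-linked genes left off), 1 panel per setting, with dark bars for lists that passed camera at both correlations, light blue for the preset one only and grey for neither. In stimulated cells 14 lists passed, with long-term HSC identity at 1.14 and lymphoid-primed progenitor genes at -1.69, against 0 in young fresh and 5 in old fresh cells.

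The comparison of KO with WT in young fresh cells addressed CD38 in stem cells at rest. Of 11548 genes 3 fell in the libraries labelled KO and 0 rose, each with adjusted p = 0.0334 by edgeR's quasi-likelihood test. Ltbp3, which binds latent TGF-beta (chromosome 19, 5740900 to 5758536), had 0 counts in KO and 55.4 ± 2.4 CPM in WT, at least 71.5-fold lower. Wwc2, a scaffold protein of the Hippo pathway, had 1 count against 157, a ratio of 182 (95% counting interval 32.1 to 7210), and the nucleobase transporter gene Slc43a3 had 2 against 171, a ratio of 98.9 (27 to 823). Among the next smallest p-values was that of the potassium channel gene Kcnk5, with 0 CPM in KO against 70.7 ± 49 CPM (adjusted p = 0.0552). None of the 34 lists passed. The smallest p belonged to the monocyte, macrophage and dendritic list (median -1.25, adjusted p = 0.24), and NAD metabolism and calcium signalling genes had medians of -0.06 and 0.12 (0.925 each). In simulated counts with the spread of these libraries this test made 19 false calls beside 14 true ones, so 3 calls do not stand out. Without WT replicate 1, the male library, or KO replicate 3 the count was 0, without WT replicate 2 it was 7 and without KO replicate 4 it was 50, and edgeR on these 4 libraries, or on the 8 fresh ones, called 0.

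In old fresh cells, where CD38 was studied in age, 4 genes rose and 1 fell in the libraries labelled KO. Ctsg, a serine protease of neutrophil granules, had 431 counts in KO (46.9 ± 5.4 CPM) and 1 count in WT, a ratio of 334 (95% counting interval 59.7 to 13200, adjusted p = 0.00108 by edgeR's quasi-likelihood test). Bnip2, which encodes a partner of BCL2, stood at 110 ± 0.51 against 5.81 ± 4.1 CPM (4.25 ± 0.58, adjusted p = 0.0113), and the zinc finger gene Zfp422 at 117 ± 9.1 against 9.69 ± 2.4 CPM (3.59 ± 0.51, 0.0146). Zfp318 had 16.7 and 127 CPM in the KO libraries and 0 counts in WT, at least 170-fold higher (0.0492). Frg1, a nuclear gene linked to RNA processing, had 0 counts in KO and 21.7 ± 0.28 CPM in WT, at least 66.3-fold lower (0.0113). The same test made 20 false calls beside 32 true ones in simulated counts. Only Ctsg passed with every library left out in turn, and the count was 9 without WT replicate 1, 27 without WT replicate 2, 3 without KO replicate 3 and 8 without KO replicate 4, with 2, 4, 2 and 3 of the 5 genes called again. EdgeR on these 4 libraries, or on the 8 fresh ones, called 0.

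Of the lists, 5 passed in old fresh cells with the preset correlation and none with an estimated one. G1/S and DNA replication genes were higher in KO (29 of 34 positive, median 0.54, adjusted p = 0.0044, and adjusted p = 0.575 with an estimated correlation). Higher too were G2/M and mitosis genes (0.42, 0.0278, and adjusted p = 0.575 with an estimated correlation) and megakaryocyte and platelet genes (0.63, 0.0352, and adjusted p = 0.575 with an estimated correlation), of which 3 rose when adjusted over the list alone. Neutrophil and granule genes were higher (median 0.70, and 1.29 with genes at 0 in 1 group placed at their bound, adjusted p = 0.016, and adjusted p = 0.592 with an estimated correlation). Ctsg alone rose over all genes and 4 of 19 rose when adjusted over the list alone. Cytosolic ribosomal protein genes were lower (34 of 40 negative, median -0.39, adjusted p = 0.00923, and adjusted p = 0.592 with an estimated correlation), 13 of them when adjusted over the list alone. NAD metabolism genes had a median of 0 (adjusted p = 0.966) and calcium signalling genes one of 0.09 with a mean of -0.26 and a test direction of down (0.754). Neither these nor the other lists passed (29 in all, smallest adjusted p = 0.121). Without WT replicate 2 all 5 calls ended (0.41, 0.49, 0.79, 0.53 and -0.24 for G1/S, G2/M, megakaryocyte, neutrophil and ribosomal protein genes, smallest adjusted p = 0.213). Without KO replicate 4 those for G1/S (0.30, adjusted p = 0.222), G2/M (0.18, 0.751), megakaryocyte (0.63, 0.0778) and ribosomal protein genes (-0.32, 0.222) ended. Without WT replicate 1 the G2/M (0.62, 0.0657) and megakaryocyte (1.19, 0.0657) calls ended while G1/S stood at 0.92 and neutrophil genes at 3.08. Without KO replicate 3 the megakaryocyte (0.27, 0.34) and neutrophil (0, 0.425) calls ended while G2/M stood at 0.69. Neutrophil transcripts differed within groups: Ngp had 108 and 12.6 CPM in the old KO libraries and 3.72 and 0 CPM in the old WT libraries.

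Whether the difference between genotypes itself changed with stimulation was tested as an interaction. The 28 identity genes shifted upwards, as KO minus WT in stimulated cells less the same in fresh cells (25 of 28 positive, median 1.05, camera adjusted p = 0.00246), and 1 member rose when adjusted over the list alone. The call ended with an estimated correlation (adjusted p = 0.266) and without young fresh WT replicate 1 (median 1.02, adjusted p = 0.0671). No single gene passed edgeR's quasi-likelihood test, 577 had an unadjusted p under 0.05 where chance gives 577, DESeq2 called 61 and voom with group weights 0. The count was 1 without young fresh WT replicate 2 and 7 without young fresh KO replicate 4. The smallest p-values belonged to Ltbp3 (adjusted p = 0.197), Kcnk5 (0.267) and Wwc2 (0.267 by edgeR), the genes near 0 in young fresh KO.

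The interaction of genotype with age passed for 4 genes by edgeR's quasi-likelihood test. Ctsg differed by 10.66 ± 1.03 (adjusted p = 0.000473), with KO minus WT at -2.64 in young and 8.01 in old cells, and Bnip2 by 5.18 ± 0.76 (0.0297), with -0.93 and 4.25. Slc43a3 differed by 7.74 ± 1.20 (0.0352), with -6.52 and 1.22. Frg1 differed by -9.69 ± 1.40 (0.0297), and its fitted values rest on the old KO libraries at 0 counts. No list passed; the ageing list (median -1.25) and the G1/S list (0.79) had the smallest adjusted p, 0.0728 each. The count of 4 was 2 without young fresh WT replicate 1, young fresh WT replicate 2 or old fresh KO replicate 4, and 1 without young fresh KO replicate 3 or old fresh KO replicate 3. It was 34 without young fresh KO replicate 4, 8 without old fresh WT replicate 1 and 25 without old fresh WT replicate 2. EdgeR on the 8 fresh libraries called 0.

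At adjusted p under 0.05 by edgeR the 3 settings had 3, 0 and 5 genes to share in young fresh, stimulated and old fresh cells, too few for an overlap to be seen. At an unadjusted p under 0.01, young and old fresh cells shared 14 genes that went the same way where 3.5 are expected, and 5 that went opposite ways (exact two-sided binomial p = 0.0636 for the split of 19). Of the 14, 12 were lower in both, with 1.74 expected, among them the ribosomal protein genes Rpl31, Rpl37, Rpl37a, Rpl38, Rps14 and Rps27. The expected numbers and the binomial test take genes as independent, which ribosomal protein genes need not be. The share of counts in ribosomal protein genes was 18.1% and 17.2% in young fresh WT against 16.7% and 16.2% in KO. In old fresh cells it was 19.9% and 22.9% in WT against 18.1% and 17.2% in KO. The other pairs of settings shared 1 gene each, with 0.283 and 0.366 expected. Across all genes, which are not independent replicates, the correlation of fold changes was -0.007 between young and old fresh cells, 0.017 between young fresh and stimulated cells and -0.066 between stimulated and old fresh cells.

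Chronological age was addressed by comparing old with young fresh cells. In WT, genes of the HSC ageing signature were higher and neutrophil granule genes lower in old libraries at the preset correlation, and neither list passed with an estimated one (adjusted p = 0.397 for both). The nuclear RNA Malat1, singled out after its values were seen, also set the young fresh libraries apart, at 531 ± 80 CPM in old against 7180 ± 2000 CPM in young WT (-3.76, adjusted p = 7.3e-06 by edgeR) and 415 ± 110 against 5060 ± 1400 CPM in KO (-3.61, adjusted p = 1.16e-05). Clca3a1 had 1109 counts in old WT and 1 in young WT, a ratio of 523 (95% counting interval 93.7 to 20700, adjusted p = 0.000936 by edgeR's quasi-likelihood test), Nupr1 stood at 183 ± 1.5 against 2.42 ± 1 CPM (6.22 ± 1.00, 0.00467). The metallothionein gene Mt2 stood at 217 ± 69 against 6.51 ± 2.1 CPM (5.05 ± 0.67, 0.000936). Gpr183, a receptor for oxysterols, had 0 counts in young WT and 140 ± 26 CPM in old WT, at least 156-fold higher (0.00581). In all 205 genes passed, 121 higher and 84 lower. The balance turned to 89 higher and 128 lower without old fresh WT replicate 2 and to 432 higher and 506 lower with DESeq2. The remaining genes with the largest rise were Uxt (at least 46.2-fold), the cyclin-dependent kinase partner gene Cks2 (5.91), Myo1c (5.48), B3galt6 (5.31) and Oxr1 (3.03). Among them too was Qsox1, an enzyme that forms disulfide bonds, at 847 ± 170 against 92.2 ± 13 CPM (3.20 ± 0.38, 0.000536). The steepest falls were in genes with 0 counts in old WT: Mob1a (at least 121-fold), Zfp318 (111), Cbl (108), Sass6 (104), Spata5 (93.1), Trmt10b (81.6), Dnajc25 (79.9), Satb1 (56.9) and Ly6c2 (42.2). Mettl6 had 2 counts against 193, a ratio of 205 (55.9 to 1700). A further 7 genes met the rule without a gene name. Floors and intervals here cover counting error only. In old fresh WT 42 genes were at 0 in 1 replicate and above 50 CPM in the other, so true falls may be smaller than these floors.

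Of the 41 ageing signature genes 7 rose in old WT and none fell, with 10 higher when adjusted over the list alone (median 2.33, and 2.46 with genes at 0 in 1 group placed at their bound, adjusted p = 4.41e-12, and adjusted p = 0.397 with an estimated correlation). By fry the adjusted p was 0.0112. Sult1a1 stood at 420 ± 57 against 84.8 ± 2.9 CPM (2.31 ± 0.44, adjusted p = 0.0125 by edgeR) and Gda, a guanine deaminase, at 419 ± 39 against 114 ± 52 CPM (1.88 ± 0.33, 0.00795). Neutrophil and granule genes were lower (19 genes, 5 fell and none rose, 8 fell and 1 rose when adjusted over the list alone, median -3.10, and -3.18 with bounds, adjusted p = 9.71e-07, and adjusted p = 0.397 with an estimated correlation). The antimicrobial gene S100a8 stood at 530 ± 340 against 4220 ± 2100 CPM (-2.99 ± 0.51, 0.00608), Camp at 7.04 ± 10 against 442 ± 30 CPM and Ngp at 1.86 ± 2.6 against 311 ± 78 CPM. The neutrophil median was -1.85 without young fresh WT replicate 1. Without old fresh WT replicate 1 it was -8.48, given without bounds. That value rests on members at 0 CPM in the remaining old WT library, Ngp and Camp among them. The other 32 lists did not pass (smallest adjusted p = 0.146), the identity list among them (median 0.43, 2 rose). The count of 205 was 54 without young fresh WT replicate 1, 107 without young fresh WT replicate 2, 126 without old fresh WT replicate 1 and 217 without old fresh WT replicate 2. In that last fit 116 of the 205 passed again. Clca3a1, Cks2, Mt2, Qsox1 and Oxr1 passed in all 4, and the other 15 of the 20 genes named by rule did not. EdgeR on the 8 fresh libraries called 86, of which 85 were among the 205, and the same test made 18 false calls beside 27 true ones in simulated counts.

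In KO, 210 genes passed between old and young fresh cells by edgeR's quasi-likelihood test, 137 higher and 73 lower. The ageing signature was again higher (4 rose, none fell, 8 rose when adjusted over the list alone, median 1.40, camera adjusted p = 0.000158, and adjusted p = 0.878 with an estimated correlation), with Clca3a1 at 214 ± 8.4 against 6.26 ± 6.7 CPM (5.09 ± 0.86, 0.00611) and Sult1a1 at 394 ± 82 against 80.2 ± 41 CPM (2.30 ± 0.43, 0.0135). Megakaryocyte and platelet genes were higher (3 of 16 rose, 4 when adjusted over the list alone, median 1.29, adjusted p = 0.0174, and adjusted p = 0.436 with an estimated correlation). Pf4 stood at 1650 ± 600 against 417 ± 200 CPM (1.99 ± 0.43, 0.0278). Plek, a substrate of protein kinase C in platelets, stood at 476 ± 160 against 121 ± 24 CPM (1.98 ± 0.32, 0.00517) and the integrin gene Itga2b at 178 ± 41 against 19.1 ± 4 CPM (3.22, 0.032). Mitochondrially encoded oxidative phosphorylation genes were lower (2 of 11 fell, 4 when adjusted over the list alone, median -0.51, 0.0375, and adjusted p = 0.436 with an estimated correlation). Lower too were neutrophil and granule genes (median -1.15, 0.0375, and adjusted p = 0.93 with an estimated correlation), where 4 fell when adjusted over the list alone and Ctsg rose (3.58 ± 0.59, 0.00542). The identity gene Hlf fell from 886 ± 140 to 384 ± 5 CPM (-1.20 ± 0.24, 0.018). The other 30 lists did not pass (smallest adjusted p = 0.217).

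The genes with the largest rise in old KO had 0 counts in young KO: the erythroid and megakaryocyte factor Gata1 (at least 111-fold), Ltbp3 (76.6), the calcium channel gene Orai1 (75.1), Klrb1c (74), Psd4 (65.8), Pbxip1 (64.9), Atg4a (62.2), Impact (57.3), Unk (53.4) and the histone methyltransferase gene Suv39h1 (49.2). Of these, 6 were also among the largest rises of stimulated over fresh KO, which used the same young fresh KO libraries, so their rises were not particular to age. Those with the largest fall had 0 counts in old KO, Akap7 (at least 446-fold), Ankrd26 (347), Frg1 (315), Atxn2 (156), Erc1 (148), Scai (71.5), Cbl (70) and Nrm (62.7), or few counts there, Mcph1 (-6.81) and Gle1 (-4.97). A further 7 genes met the rule without a name. The floors again cover counting error only, and in young fresh KO 126 genes were at 0 in 1 replicate and above 50 CPM in the other. The count of 210 was 227 without young fresh KO replicate 3 (126 of the 210 among them), 332 without young fresh KO replicate 4, 92 without old fresh KO replicate 3 and 139 without old fresh KO replicate 4, and 7 of the 20 genes named by rule passed edgeR's test in all 4. On the 8 fresh libraries 93 genes passed, all of them among the 210. Of the list calls, none held without young fresh KO replicate 3, with the ageing list at 1.74 (adjusted p = 0.0999), megakaryocyte genes at 1.45 (0.153), mitochondrially encoded genes at -0.53 (0.148) and neutrophil genes at -1.67 (0.148). Without young fresh KO replicate 4 the ageing list stood at 2.91, megakaryocyte genes at 2.19 and neutrophil genes at -0.27 (adjusted p = 0.15). Without old fresh KO replicate 3 megakaryocyte genes stood at 0.82 (0.18), mitochondrially encoded genes at -0.58 (0.0699) and neutrophil genes at -3.15. Without old fresh KO replicate 4 the ageing list stood at 0.75, mitochondrially encoded genes at -0.54 (0.188) and neutrophil genes at -1.29 (0.794). In simulated counts this test made 32 false calls beside 29 true ones.

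**Figure D4:**
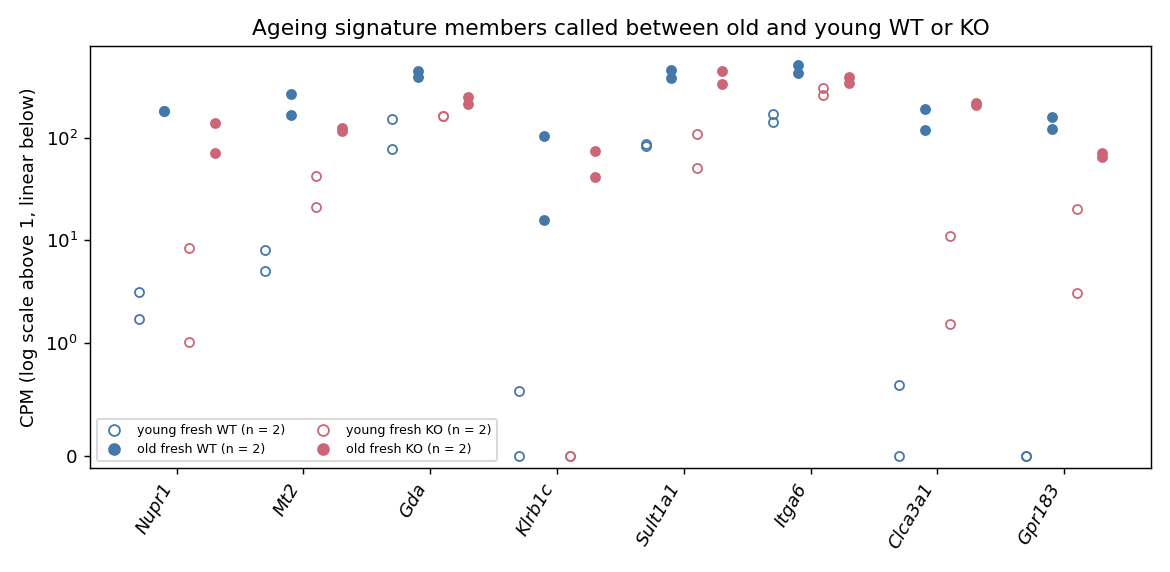
Levels in CPM (vertical axis, log above 1 and linear below) of HSC ageing signature genes that changed with age in WT or KO (horizontal axis), with 1 point per fresh library, open for young and filled for old, coloured by genotype. Sult1a1 lies at 420 ± 57 and 394 ± 82 CPM in old WT and KO, above 84.8 ± 2.9 and 80.2 ± 41 CPM in young WT and KO (SD, n = 2).

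Whether loss of CD38 turned back the change with age was asked across genes. The correlation between the change from young to old in WT and the change from WT to KO in old cells was -0.489 across 11548 genes, which are not independent replicates. The old WT libraries enter both with opposite signs, and counts simulated without any effect gave -0.52 on average (-0.535 to -0.504 in 50 simulations). The covariance was -1.27 against -1.29 in the simulations (SD 0.027), so no turning back was seen beyond that shared term. Among 9695 genes with a mean of at least 5 CPM the correlation was -0.486 against -0.523 in the simulations, and the covariance -1.22 against -1.33 (SD 0.028). In each gene set the observed correlation was weaker than in any simulation. The covariance, which carries the shared term, was weaker than simulated by more than its SD only at 5 CPM or more. There the simulations may have overstated the shared term, and a small turning back could be hidden. With libraries left out in turn the correlation ran from -0.673 to -0.387. For the ageing signature itself the median of KO minus WT in old cells was -0.75 (camera adjusted p = 0.157).

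The response of young cells to cytokines was addressed by comparing stimulated with fresh libraries. Stimulation went with the complexity of the libraries. At equal depth 12463 to 12706 genes were detected in stimulated and 8907 to 9753 in young fresh libraries. In WT and KO alike, a rise from 0 counts in fresh cells can therefore not be told from better detection. In WT, 92 genes passed edgeR's quasi-likelihood test, 25 higher and 67 lower after stimulation. Identity genes were lower (25 of 28 negative, 6 fell, 16 when adjusted over the list alone, median -1.69, camera adjusted p = 5.49e-14, and adjusted p = 0.00755 with an estimated correlation). Sult1a1 stood at 6.62 ± 2.3 against 84.8 ± 2.9 CPM (-3.67 ± 0.48, 0.00217). Prdm16, a transcription factor of stem cell maintenance, stood at 13.8 ± 0.16 against 99.2 ± 17 CPM (-2.85, 0.0248) and the niche factor gene Angpt1 at 401 ± 15 against 946 ± 130 CPM (-1.24 ± 0.24, 0.0204). The neutrophil and granule list did not pass (median -2.40, mean 0.03, adjusted p = 0.501), and its members went both ways, with 3 higher and 1 lower over all genes. Mpo, the myeloperoxidase gene, rose, at 978 ± 160 against 49.2 ± 16 CPM (4.31 ± 0.94, 0.0484). In the same list Ctsg stood at 557 ± 10 against 24.6 ± 19 CPM (4.51 ± 0.55, 0.00115) and Prtn3 at 598 ± 66 against 54.7 ± 9.9 CPM (3.45 ± 0.50, 0.00404), although S100a8 fell from 4220 ± 2100 to 802 ± 270 CPM (-2.40, 0.0352). The mitotic kinase gene Plk1 rose from 24.4 ± 12 to 208 ± 23 CPM (3.08 ± 0.56, 0.0156) and Flt3 from 16 ± 12 to 189 ± 73 CPM (3.55 ± 0.72, 0.0318). Dntt, Prg2, Cst7 and Uxt had 0 counts in fresh WT and were at least 635-fold, 605-fold, 105-fold and 43.4-fold higher, and Plac8 rose by 3.77. The largest other falls were in Rgag4 (-3.87), Abcg3 (-3.45), the nuclear RNA Malat1, at 990 ± 140 against 7180 ± 2000 CPM (-2.86 ± 0.26, 8.45e-05), Chtf8 (-2.70), Aldh1a1 (-2.68), Kdelr1 (-2.36) and Tbxas1 (-2.30). A further 2 genes met the rule without a name.

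The other 7 lists that passed in this comparison passed with the preset correlation only. Higher were lymphoid-primed genes (median 3.13, and 2.61 with bounds, 2 of 17 rose, adjusted p = 9.38e-05, and adjusted p = 0.141 with an estimated correlation) and B cell genes (5.37, and 3.19 with bounds, none of 10 passed, 1e-04, and adjusted p = 0.23 with an estimated correlation). So were mast cell and basophil genes (4.00, and 3.77 with bounds, none of 9 rose and Slc18a2 fell, 1e-04, and adjusted p = 0.0625 with an estimated correlation) and immediate early genes (1.11, and 1.05 with bounds, none of 23 passed, 0.0132, and adjusted p = 0.321 with an estimated correlation). G2/M genes were higher as well (0.81, 1 of 31 rose, 3 when adjusted over the list alone, 0.0132, and adjusted p = 0.23 with an estimated correlation). Lower were ribosomal protein genes (-0.24, 7 of 40 fell, 12 fell and 1 rose when adjusted over the list alone, 0.000163, and adjusted p = 0.321 with an estimated correlation) and mitochondrially encoded genes (-0.46, 2 of 11 fell, 0.0132, and adjusted p = 0.176 with an estimated correlation). The other 26 lists did not pass (smallest adjusted p = 0.129). The count of 92 was 32 without young fresh WT replicate 1, 38 without young fresh WT replicate 2, 44 without young stimulated WT replicate 1 and 35 without young stimulated WT replicate 2. Ctsg, Rgag4, Sult1a1, Malat1, Chtf8 and Tbxas1 of the 20 genes named by rule passed edgeR's test in all 4. Without young fresh WT replicate 1 the calls for G2/M (0.70, adjusted p = 0.0744) and mitochondrially encoded genes (-0.35, 0.0744) ended. Without young fresh WT replicate 2 those for G2/M (0.87, 0.0546), mitochondrially encoded (-0.36, 0.144) and immediate early genes (1.51, 0.187) did, while mast cell genes stood at 7.31. Without young stimulated WT replicate 1 the mitochondrially encoded call ended (-0.24, 0.0783) and the ribosomal protein list stood at -0.13. EdgeR on these 4 libraries alone called 0 genes.

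In KO, 75 genes passed between stimulated and fresh cells by edgeR's quasi-likelihood test, 39 higher and 36 lower. The balance depended on the method, with 37 higher and 50 lower under RLE scaling, 311 and 192 with DESeq2 and 9 and 111 with voom and group weights. Identity genes were lower as a list (23 of 28 negative, none passed alone, median -0.55, camera adjusted p = 0.000711, and adjusted p = 0.138 with an estimated correlation). The largest rises were in genes with 0 counts in fresh KO, led by Cst7, an inhibitor of cathepsins (at least 78.2-fold, 0.0302), Suv39h1 (68.1) and the cell cycle transcription factor gene E2f1 (60.5). Next came Pbxip1 (54.9), Psd4 (49.5), Impact (46.9), Mydgf (40.8), Orai1 (38.1), Kcnk5 (27.1) and Ltbp3 (21.9). Of these, Suv39h1, Pbxip1, Psd4, Impact, Orai1 and Ltbp3 were also among the largest rises of old over young KO, a comparison with the same young fresh KO libraries at 0, so their rises were not particular to stimulation. Among the largest falls were those in the antimicrobial gene S100a9, from 2130 ± 550 to 193 ± 33 CPM (-3.47 ± 0.73, 0.0432), Rgag4 (-2.69), Pigp (-2.60) and Chtf8 (-2.57). Malat1 fell from 5060 ± 1400 to 1030 ± 4.6 CPM (-2.29 ± 0.25, 0.000725), and other falls were in Rps7 (-1.91, 2.85e-05), Ubxn7 (-1.62) and Arih1 (-1.57). A further gene met the rule without a name. Among the other lists, mast cell and basophil genes (median 5.50, and 2.68 with bounds, adjusted p = 0.00553, and adjusted p = 0.138 with an estimated correlation), monocyte genes (1.75, 0.00857, and adjusted p = 0.47 with an estimated correlation) and lymphoid-primed genes (2.52, and 2.19 with bounds, 0.0396, and adjusted p = 0.47 with an estimated correlation) were higher with no member past the test over all genes. Lower were mitochondrially encoded genes (-0.56, 2 of 11 fell, 0.00553, and adjusted p = 0.138 with an estimated correlation), ribosomal protein genes (-0.15, 5 of 40 fell and 2 rose, 0.00449, and adjusted p = 0.52 with an estimated correlation) and interferon genes (median -0.56, mean -0.05, none passed, 0.00857, and adjusted p = 0.47 with an estimated correlation). The other 27 lists did not pass (smallest adjusted p = 0.101).

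The count in KO was 79 without young fresh KO replicate 3 (38 of the 75 genes among them), 120 without young fresh KO replicate 4, 31 without young stimulated KO replicate 3 and 46 without young stimulated KO replicate 4. Suv39h1, Ltbp3, Chtf8, Malat1 and Rps7 of the 20 genes named by rule passed edgeR's test in all 4. Without young fresh KO replicate 3 the calls for mitochondrially encoded (-0.41, adjusted p = 0.0533), interferon (-0.55, 0.0548), ribosomal protein (-0.08, 0.0589), mast cell (6.02, 0.0574) and lymphoid-primed genes (4.02, 0.0574) ended, and monocyte genes stood at 3.11. Without young fresh KO replicate 4 those for mast cell (6.07, 0.0523) and lymphoid-primed genes (3.23, 0.37) ended, with monocyte genes at 5.88 and interferon genes at -0.15. Without young stimulated KO replicate 3 the lymphoid-primed call ended (2.03, 0.0571), with identity genes at -0.35, interferon genes at -0.89, monocyte genes at 2.80 and mast cell genes at 3.25. EdgeR on these 4 libraries alone called 0 genes.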

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

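The test of genes linked to Cd38, and the comparison of length and GC between genes called higher and lower with age, were chosen only after the results were seen.

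The long-term HSC identity list drew attention because its genotype difference itself differed between stimulated and fresh cells, by a median of 1.05 (camera adjusted p = 0.00246), a call lost with an estimated correlation (0.266) and without young fresh WT replicate 1 (0.0671). Its median was 1.14 in stimulated and 0.03 in young fresh cells, and 129 genes passed in the 4-library fit of stimulated cells. A difference in depth between the stimulated libraries is argued against by their totals. These were 2792521 and 2801629 in WT, and 3249721 and 2692245 in KO, on either side of WT. After thinning to equal totals 96.1% of these genes (124 of 129) were called again with the same sign. Thinning took away few counts, so that result adds little. Megakaryocyte or platelet RNA in the KO libraries stays open, because the identity list rose only 0.31 more than the megakaryocyte list, against SEs of 0.12 and 0.2 (past the bound set beforehand, the larger SE, by less than the spread of the difference), and over 12 libraries the medians came closer without stimulated WT replicate 2 (0.98 and 0.83) and without stimulated KO replicate 4 (0.86 and 0.68). Few of the called genes lay near Cd38, with 1.63% of those with a position (2 of 123) within 20 Mb of it. That window held only 128 tested genes, so it could hardly have held most of the calls. Linked sequence that acts on genes elsewhere would not show there, so sequence linked to the Cd38 allele stays open as a source. Strain differences elsewhere in the genome were not tested. A shift in cell composition or an effect of genotype on stem cell state may remain as hypotheses.

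Ctsg drew attention because its genotype difference changed between young and old fresh cells, by 10.66, as did those of Bnip2 by 5.18, Slc43a3 by 7.74 and Frg1 by -9.69. Ctsg, Slc43a3 and Frg1 each had 2 counts or fewer in at least 1 of these groups. Dropout in libraries of low complexity may account for such genes in young cells: 28 genes were at 0 in both libraries of a genotype and above 20 CPM in both of the other, and the 2 regroupings of the same 4 libraries gave 28 and 25. In old cells the real grouping gave 21 and the regroupings 19 and 15, too few groupings to decide, so dropout and an effect of genotype cannot be told apart there.

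The rise of ageing signature genes in old WT cells was weighed because age went with the library set. A difference in depth between library sets is argued against, since 100% of the 205 called genes kept their sign at an unadjusted p under 0.01 by edgeR after thinning the 8 fresh libraries to equal totals, where 196 genes were called. A smooth trend on the length and GC of each gene's longest transcript is argued against as the main source. Over all tested genes the fold change hardly followed them (Spearman correlations of 0.025 and 0.029). The libraries held tags of the 3′ end, so a bias on the tagged end alone was not covered. Removing the trend took at most 27.4% of the fold change of a called gene, so that 100% of the 202 with a matched transcript kept more than 50%. Among these genes (n = 202) those called higher did have shorter transcripts than those called lower (median 2724 against 3295 bases, Wilcoxon p = 0.016) and more GC (48.3% against 45.1%, p = 0.00442), so a small share of such bias may remain. Other differences between the sets, such as the day of sorting, were not given in the labels and may remain beside age itself, which is a hypothesis for these genes.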

How the results depend on the processing

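Limma voom with group weights, the 8 fresh libraries alone, list tests with a replicate block or on the libraries of a contrast alone, and the linked genes and left-out libraries of the 4-library stimulated fit were chosen only after the results were seen.

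No called list median took the opposite sign under any alternative run, though that of neutrophil genes in old fresh cells was 0 without KO replicate 3. No called fold change of a named gene changed sign either. The naming rule asked for both libraries of a group above both of the other. Leaving a library out could therefore hardly turn a gene named by it, and its sign there is no test. Counts of changed genes are given in the order KO against WT in young fresh, stimulated and old fresh cells, old against young in WT and KO, stimulated against fresh in WT and KO, and the interactions with stimulation and age. The 12-library edgeR counts were 3, 0, 5, 205, 210, 92, 75, 0 and 4. Without a filter they were 61, 9, 79, 423, 478, 184, 241, 10 and 80. DESeq2 gave 434, 4, 492, 938, 1117, 370, 503, 61 and 432, among them all 3, 5, 205, 210, 75 and 4 of the edgeR calls and 90 of the 92. The libraries of each contrast alone gave 0, 129, 0, 28, 5, 0 and 0, and the 8 libraries of each interaction 0 and 0. Voom with group weights gave 0, 227, 2, 69, 42, 260, 120, 0 and 0, with weights of 4.34 and 4.73 for stimulated and 0.355 to 0.715 for fresh groups. The 8 fresh libraries gave 0, 0, 86 and 93 for genotype in young and old cells and for age in WT and KO. RLE scaling left every count within 1.5 times of these. It moved the median of all genes by at most 0.07. The balance of higher and lower genes did turn: from 121 and 84 to 432 and 506 with DESeq2 and 89 and 128 without old fresh WT replicate 2 for age in WT, from 39 and 36 to 37 and 50 with RLE scaling and 9 and 111 with voom for stimulation in KO, and from 4 and 1 to 245 and 247 with DESeq2 and 0 and 2 with voom for KO in old cells. The 12-library fit had a common dispersion of 0.705, against 0.0327 and 0.0391 in stimulated groups and 0.963 or more in fresh ones. It was thus too large for the stimulated groups and too small for the fresh ones. For KO against WT, unadjusted p under 0.05 numbered 57 in stimulated, 1236 in young fresh and 1282 in old fresh cells. Chance gives 577 in each. Fits with fewer libraries have fewer degrees of freedom, which cannot alone account for 129 stimulated calls against 0. Other causes of these differences were not tested.

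The labels did not say whether the numbers in the sample titles pair the samples. Deviations of groups that share numbers correlated at -0.013 to 0.012 across genes, which gave no sign of pairing, but the spread between fresh replicates could hide it. For number 1 in WT the sex differed. Xist had 0 counts in young fresh WT replicate 1 and 610 CPM in stimulated WT replicate 1, so these libraries did not share an animal. Pairing under the other numbers, or by handling, stays open. A replicate block takes equal numbers as pairs. It gave 336 and 362 genes for age in WT and KO, and 155 and 202 for stimulation in WT and KO. The interaction with stimulation had 0 and that with age 28. Under the block 2 of the 4 list calls for age in KO were kept, with mitochondrially encoded genes at -0.51 and neutrophil genes at -1.31 (adjusted p = 0.0742 each), and all list calls of the other contrasts with a block were kept.

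With libraries left out in turn (without each replicate of a contrast), where a lone sample is assumed to vary like the other groups, counts ran from 0 to 50 for KO in young fresh cells, 0 to 0 in stimulated cells, 3 to 27 in old fresh cells, 54 to 217 and 92 to 332 for age in WT and KO, 32 to 44 and 31 to 120 for stimulation in WT and KO, and 0 to 7 and 1 to 34 for the interactions. The 4-library stimulated fit ran from 24 to 296. The ageing list ran from 1.81 to 2.88 in old WT and 0.75 to 2.91 in old KO, and its call in old KO ended without young fresh KO replicate 3. In stimulated KO the identity list ran from 0.86 to 1.36, the ageing list from 0.94 to 2.19 and the lymphoid-primed list from -2.02 to -0.68, all past the threshold.

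With an estimated correlation the ageing list kept its medians of 2.33 in old WT and 1.40 in old KO and lost its calls by limma's camera (adjusted p = 0.397 and 0.878). Of 41 list calls under an estimated correlation 7 held, of 238 under other settings 213 held, and of 168 with a library left out 113 held. RLE scaling kept 13 of the 14 list calls in stimulated KO, and no filter kept 6. Of 897 values of named genes under other settings 688 kept their side of the threshold and their direction.

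Shared genotype effects numbered 0 at adjusted p, and at unadjusted p under 0.01 they were 1 for young fresh and stimulated, 14 for young and old fresh and 1 for stimulated and old fresh cells, with 100%, 73.7% and 100% of one sign. The correlation of the age change with the KO change in old cells was -0.486 at 5 CPM or more (-0.523 in simulations without effect) and -0.673 to -0.387 with libraries left out. Among the 205 genes called for age in WT it was -0.73, which says nothing on a turning back, since these genes were chosen on the old WT libraries that enter both changes and no simulated value was made for them. Among genes within 10 Mb of Cd38 0 were called over 12 libraries and 2 in the 4-library stimulated fit. At the depth of 1600155 to 5164720 counts, genes with few counts in fresh cells could not be told from absent ones.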

Other observations

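All values in this part on Prg2, Ear1, Ear6 and Epx and on genes near Cd38 in the 4-library fit were chosen only after the result was seen.

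Prg2, Ear1, Ear6 and Epx were picked because they were called lower in the stimulated libraries labelled KO in the 4-library fit by edgeR's quasi-likelihood test, and no list that holds them was tested. Prg2 stood at 199 ± 12 CPM in KO and 542 ± 160 CPM in WT (-1.42 ± 0.17, adjusted p = 0.0011). Ear1 stood at 5.91 ± 1.8 and 38.5 ± 6.3 CPM (-2.66 ± 0.35, adjusted p = 0.0024), Ear6 at 15.2 ± 0.04 and 54 ± 8.3 CPM (-1.80 ± 0.27, adjusted p = 0.00386) and Epx at 15.2 ± 2 and 47.9 ± 10 CPM (-1.64 ± 0.28, adjusted p = 0.0114). All 4 had 0 counts in the young fresh libraries. In old fresh cells the order of the genotypes was the other way for Prg2, at 30 ± 42 CPM in KO (0 and 60), and Ear1, at 9.43 ± 8.9 CPM in KO (15.8 and 3.1), both with 0 CPM in WT. Without KO replicate 3 Prg2 (-1.48, adjusted p = 0.0537 by edgeR), Ear6 (-1.79, 0.071) and Epx (-1.50, 0.149) no longer passed, while Ear1 passed with each of the 4 libraries left out.

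Genes within 10 Mb of Cd38 were tested for an excess of calls between genotypes. Over 12 libraries 0 of 68 were called in each setting. In the 4-library stimulated fit 2 of 56 were called against 121 of 9963 elsewhere (Fisher's exact p = 0.15), namely Cc2d2a, 0.19 Mb away (2.03 ± 0.41), and Evc2, 6.51 Mb away, with 0 counts in both WT libraries and 14 and 32 in the KO libraries. Cc2d2a no longer passed edgeR's test without KO replicate 3 (adjusted p = 0.0924) or KO replicate 4 (0.361), and Evc2 did not without WT replicate 2 (0.0796) or KO replicate 3 (0.11). With windows of 5 and 20 Mb Fisher's exact p was 0.159 and 0.672.

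The 12 genes lower in KO in both young and old fresh cells at an unadjusted p under 0.01 were Dennd1a, Rpl37a, Sun2, Eif4ebp1, Rps14, Rpl38, Rpl37, Ptpn18, Rpl31, Wdr5b, Csnk2a1 and Rps27, and the 2 higher in both were Top1 and Stx18. None had an adjusted p under 0.05 by edgeR in either setting.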
